A study of Halobacterium salinarum NRC-1 with 12 samples.

How the data were processed

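Transcript levels of Halobacterium salinarum, a salt-loving archaeon, were measured on 2-colour Agilent oligonucleotide arrays in 12 cultures. The cultures were of a strain lacking the histone gene hpyA in a Δura3 background (called the hpyA deletion strain below) and of its Δura3 parent, each in log and in stationary phase, with 3 biological replicates per group. Per the labels, RNA of each culture was hybridised together with RNA of a common reference, the strain NRC-1 in log phase, on 2 arrays with the dyes exchanged, giving 24 arrays. Growth phase and strain were taken from the sample titles. Every sample's description speaks of a mid-log culture and of another growth temperature than the growth protocol, also for the stationary samples, so the descriptions were not used for grouping, and the temperature is not given here.

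The authors deposited 1 scanner file per array and a table of processed values. Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.3.1 and hold the signal intensity of each spot and of its local background in both dyes, in intensity units with no normalization. They also hold the log10 ratio of red over green of the background-subtracted and dye-normalized signals, per the file headers. The deposited value table holds log2 ratios, 1 column per sample over both dye orientations, and 0 of its columns had no sample. The submitters' processing notes name limma, without a version, and the other steps behind that table are not given in the sources used here. Set against the values computed from the scanner files, its columns correlated across loci at 0.936 to 0.99, with slopes of 0.888 to 1.05 and column medians from -0.0578 to 0.0543. Its scale was therefore log2, its direction sample over reference, and its loci were not centred on their own mean.

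The dye that carried the sample on each array was read from the authors' list of dyes. Background was corrected with normexp (offset 50) on mean spot and median local background signals. Each array was then normalized with loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as outliers by the scanner software (8749 gene spots over all arrays, 2.4%) were left out, as were control spots after the background step. No spot was saturated on any array. The sign of each ratio was turned so that positive values mean more RNA in the sample than in the reference. The 6 or 7 spots of each locus carry 1 probe sequence and were averaged (1662 loci with 6 spots and 748 with 7), and both arrays of a sample were averaged into 1 value, so that a culture counted once. All 2410 loci on the arrays were tested, with no filter on dim loci.

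A locus was called well above background on an array where at least 0.5 of its spots carried the scanner software's mark for that channel. Where a locus was not well above background on any array of 1 group, a lower bound of its fold is given beside the fitted value, which is itself no bound. The bound divides the brighter group's mean signal by that of the dimmer group, with the dimmer signal raised on each array to the lowest signal among loci well above background. These signals were taken per channel after loess and between-array quantile normalization of mean intensity. The bound is a ratio of group means under 1 processing and makes no allowance for the spread between cultures. The number of arrays limits the precision of every value.

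Groups were compared in a single limma fit of 4 group means to the 12 samples, so that the groups shared 1 estimate of the spread, with 8 residual and 2.642 prior degrees of freedom. The 5 contrasts were the strain difference in log phase, the strain difference in stationary phase, the difference between these, and the change from log to stationary phase in each strain. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 over the 2410 loci of a contrast, in the two-sided moderated test of limma. Errors of fold changes are standard errors (SE) of that fit, and errors of group values are standard deviations (SD) over 3 samples. The design, the contrasts, the loci to be named, the gene lists and the alternatives were fixed before the data were examined, except where the closing section says otherwise.

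The rule for named loci took, in each contrast, the 8 largest rises and the 8 largest falls among called loci whose groups did not overlap (overlap was not considered for the difference of differences). Where under 5 loci were called it took the 10 with the smallest raw p, and it always took the deleted genes hpyA and ura3 (pyrF). The arrays give loci only as VNG numbers of strain NRC-1. The reference gene table belongs to another strain, 91-R6, and 0 of its entries carry a VNG number, so the files do not pair loci with gene names. Therefore no gene name or function is given, at most 2 rising and 2 falling loci are printed per contrast, and the parts of the rule that needed gene functions could not be used. The numbers of hpyA (VNG0134G) and ura3 (VNG1673G) and the meaning of locus numbers from 5000 upward, which belong to the plasmids, come from general knowledge of this genome.

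Of the 26 gene lists fixed beforehand, 1 could be formed, the plasmid-borne loci. The other 25, among them ribosomal proteins, gas vesicles and transposases, needed names or products. The plasmid list was tested against the remaining loci with camera, with a preset and with an estimated correlation between loci, and with Fisher's exact test on called loci, which takes loci as independent. The fry test, in contrast, set the plasmid loci against no change rather than against the other loci. The arrays lay on 3 slides, each with 8 arrays and 1 sample of each group, so each contrast was also computed within each slide and with slide as a block. Correlations across loci are given without p-values, since loci are not independent replicates. The exception is the correlation between adjacent loci, which was set against shuffles of the loci. The slope of the phase change in the deletion strain on that in the parent was fitted by total least squares. The labels do not say that equal replicate numbers mark a shared culture or day, so no fit was paired at first. Deviations from the group means correlated between equal numbers at 0.388 to 0.74 in 3 of 3 pairs of log and stationary samples of the deletion strain. By this hint from the data those numbers may pair the samples, but deviations within a group of 3 are not independent, so it is not settled. In the other contrasts of 2 groups 1 or more of the 3 pairs did not exceed 0.1. Each sample was also placed on the axis from the mean of the log samples to the mean of the stationary samples, computed without that sample, and the positions were compared by exact permutation tests.

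Alternatives covered the scanner software's processed signals, no background correction, a normexp offset of 10, median centring in place of loess, scale normalization between arrays, the median over spots, outlier spots kept, the authors' values, and a filter that kept loci well above background in at least 1 channel on 12 or more arrays (984 loci). They also covered slide and replicate number as blocks, all 24 arrays fitted with sample as a random block, only the contrast's groups in the fit, a trended robust variance, a stricter adjusted p, a minimum fold, and each sample or slide left out. The fit was tested on simulated data with the fitted spread of each locus and 200 changed loci per contrast. In the 5 contrasts it called 74.6 to 88.1% of loci changed by 0.5 on the log2 scale, 94 to 100% of those changed by 1, 98.5 to 100% of those changed by 2, and 9 to 16 unchanged loci. The simulated noise was independent between loci and cultures, with no slide effect or other shared structure. These shares and counts therefore need not hold for the measured cultures.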

Results

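RNA of 12 Halobacterium salinarum cultures was measured: the hpyA deletion strain and its Δura3 parent, in log and in stationary phase, with 3 cultures in each of the 4 groups. HpyA is the histone of this archaeon. Each culture was compared on 2 dye-exchanged arrays with a log-phase NRC-1 reference, so a value of 0 on the log2 scale means equal RNA in culture and reference. The signal was low: per array, 5.69 to 50.1% of loci (median 34.8%) were well above background in the sample channel and 8.09 to 53.7% in the reference channel. The median gene spot was 1.13 to 1.22 times as bright as the median negative control in green and 1.07 to 1.17 times in red. Per group, 29.3% ± 17.2 of loci (SD, n = 3) were well above background in log cultures of the deletion strain and 25.2% ± 2.78 in those of the parent. In stationary cultures these shares were 39.4% ± 3.37 and 29.1% ± 5.20. Log replicate 3 of the deletion strain had the lowest share, 9.54%. Both dye-exchanged arrays of a culture correlated across loci at -0.327 to 0.633 (median 0.365). Arrays of different cultures with the sample in Cy5 correlated at -0.125 to 0.956, and with the sample in Cy3 at 0.161 to 0.951. Across loci, cultures of a group correlated at 0.894 to 0.933 in the stationary parent, 0.799 to 0.897 in the stationary deletion strain, 0.627 to 0.855 in the log deletion strain and 0.487 to 0.932 in the log parent.

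The deleted genes served as a check of the strains. VNG1673G, the ura3 (pyrF) gene that both strains lack, was below the NRC-1 reference in 12 of 12 cultures, with a mean log2 ratio of -0.23 ± 0.10 (SD, n = 12, range -0.41 to -0.08). It was well above background on 6 of 24 arrays in the reference channel and on 0 in the sample channel. Its mean lay at percentile 5.98 among all loci, so a value this low is not particular to a deleted gene. As both strains lack the gene, it cannot tell them apart. VNG0134G, the histone gene hpyA, had a mean log2 ratio of -0.02 ± 0.07 (SD, n = 12, range -0.12 to 0.13). It was well above background on 0 arrays in either channel, the reference included, so its probe could not show the deletion.

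The first comparison asked whether loss of the histone gene changed transcript levels in log phase. VNG5192H, a plasmid locus, was lower in the deletion strain, at -1.15 ± 0.05 against 0.28 ± 0.30 in the parent (log2 ratio to the reference, SD, n = 3). Its log2 difference was -1.42 (SE 0.17, adjusted p = 0.0140), with -1.51, -1.63 and -1.13 on slides 1, 2 and 3, and it was lower in 3 of 3 deletion cultures than in any parent culture. It was not well above background on any array of the log deletion strain and was so on 3 of 6 parent arrays. By the bound described above, the fall was therefore at least 1.07-fold. VNG6325H had the next smallest raw p and did not pass the test, with a log2 difference of -0.92 (SE 0.15, adjusted p = 0.0858; -0.97, -1.09 and -0.71 by slide). Of the 2410 loci tested with limma, 1 was called, also with slide as a block, while 269 had a raw p under 0.05, where chance alone gives 120.5. The groups did not overlap at 10.5% of loci, where chance gives 10%. The call was lost with deletion replicate 1, 2 or 3 or parent replicate 2 or 3 left out in turn (adjusted p of VNG5192H from 0.0654 to 0.115, 0 loci called, and 3.23e-05 to 0.952 over all its 23 alternatives, with log2 differences from -2.18 to -0.33). Without parent replicate 1, in contrast, 247 loci were called.

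In stationary phase, 33 loci differed between the strains, 23 of them higher and 10 lower in the deletion strain. VNG5192H was lower here too, at -1.09 ± 0.30 against 0.30 ± 0.20 (SD, n = 3), a log2 difference of -1.39 (SE 0.17, adjusted p = 0.00554; -1.39, -0.99 and -1.79 by slide). It was not well above background on any array of the stationary deletion strain, which makes the fall at least 1.44-fold. Its call was lost with only the contrast's groups in the fit (adjusted p = 0.0539), without slide 1 (0.0913) and without slide 2 (0.0802), out of 1.2e-05 to 0.0913 over its 23 alternatives, with log2 differences from -2.43 to -0.30. VNG6275H, another plasmid locus, stood at 2.43 ± 0.01 in the deletion strain and 3.58 ± 0.05 in the parent, a log2 difference of -1.15 (SE 0.14, adjusted p = 0.00554; -1.21, -1.10 and -1.13 by slide). Higher in the deletion strain were VNG6224H, by 1.47 (SE 0.27, adjusted p = 0.0280; 1.37, 1.96 and 1.08 by slide), and VNG2451H, by 1.40 (SE 0.28, adjusted p = 0.0398; 1.09, 1.97 and 1.15 by slide). VNG6224H was called in 12 of its 23 alternatives (adjusted p from 0.000263 to 0.45) and VNG2451H in 11. Neither was called without background correction (differences of 0.41 and 0.34, adjusted p = 0.146 and 0.141), with median centring (0.0653 and 0.102) or with only the contrast's groups in the fit (0.142 for both). The same held without slide 1 (0.0578 and 0.122), slide 2 (0.45 and 0.53) or slide 3 (0.0707 and 0.0603). VNG6224H was at -0.29 ± 0.55 in the deletion strain and -1.76 ± 0.47 in the parent, and VNG2451H at -0.43 ± 0.52 and -1.83 ± 0.44 (SD, n = 3).

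Of the 33 loci, 27 passed the filter on dim loci, and 8 had an absolute log2 difference of 1 or more. In limma, 310 loci had a raw p under 0.05, and the groups did not overlap at 23.6% of loci. The share of loci well above background also differed, 39.4% in the deletion strain against 29.1% in the parent. With slide as a block 17 loci were called, and VNG2451H was no longer among them (adjusted p = 0.0893, 0.000301 to 0.53 over its 23 alternatives). The difference of VNG6275H was -0.11 with the authors' values (adjusted p = 0.692) and -0.45 with median centring (adjusted p = 0.305), and it was also not called without slide 1 (0.0856) or slide 2 (0.168), out of 0.000271 to 0.692 over its 23 alternatives. The count fell to 8 without deletion replicate 1, 9 without parent replicate 2 and 8 without parent replicate 3, and rose to 77 without deletion replicate 3. With deletion replicate 1 or 2 or parent replicate 2 or 3 left out in turn, VNG6224H (adjusted p from 0.0631 to 0.12) and VNG2451H (0.116 to 0.192) were not called.

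The third comparison asked whether the strain difference itself changed with growth phase, and 5 loci were called, 4 of them with a more positive difference in stationary phase. VNG1815G changed by 1.99 (SE 0.32, adjusted p = 0.0379; 1.85, 2.54 and 1.57 by slide). Its log2 ratio went from 0.51 ± 0.34 in log to -2.11 ± 0.45 in stationary phase in the parent, and from -0.22 ± 0.17 to -0.85 ± 0.23 in the deletion strain (SD, n = 3). It was well above background on 1 of 6 stationary parent arrays, against 6 of 6 in each other group. The sizes of its fall in the parent and of the change of 1.99 are therefore uncertain. VNG2535H changed by 1.88 (SE 0.29, adjusted p = 0.0379; 1.56, 2.34 and 1.75 by slide), with 0.68 ± 0.16 and -0.24 ± 0.43 in the parent and 0.20 ± 0.25 and 1.16 ± 0.26 in the deletion strain. VNG1317H went the other way, by -1.26 (SE 0.19, adjusted p = 0.0379; -0.90, -1.34 and -1.53 by slide), with -0.28 ± 0.17 and 0.88 ± 0.20 in the parent and 0.08 ± 0.23 and -0.01 ± 0.11 in the deletion strain. Over the alternatives the change went from 0.46 to 2.49 for VNG1815G, 0.62 to 2.14 for VNG2535H and -1.44 to -0.37 for VNG1317H.

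The raw p was under 0.05 at 482 loci in this limma contrast. With slide as a block 1 locus was called, VNG1317H (adjusted p = 0.0424), and VNG1815G (0.105) and VNG2535H (0.0891) were not. The count was 441 without parent log replicate 1, 55 without deletion stationary replicate 3 and 10 without parent stationary replicate 1. It was 1 without deletion stationary replicate 1, 2 without deletion stationary replicate 2, and 0 with deletion log replicate 2 or 3, parent log replicate 2 or 3, or parent stationary replicate 2 or 3 left out in turn. In these 8 last-named fits VNG1815G, VNG2535H and VNG1317H had adjusted p from 0.0683 to 0.168, and without deletion log replicate 1 VNG1815G was lost (0.0695). With median centring 0 loci were called and VNG1317H had a difference of -0.37. Over the 29 alternatives adjusted p went from 0.00146 to 0.769 for VNG1815G, 3.67e-05 to 0.769 for VNG2535H and 0.00239 to 0.722 for VNG1317H.

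**Figure D1:**
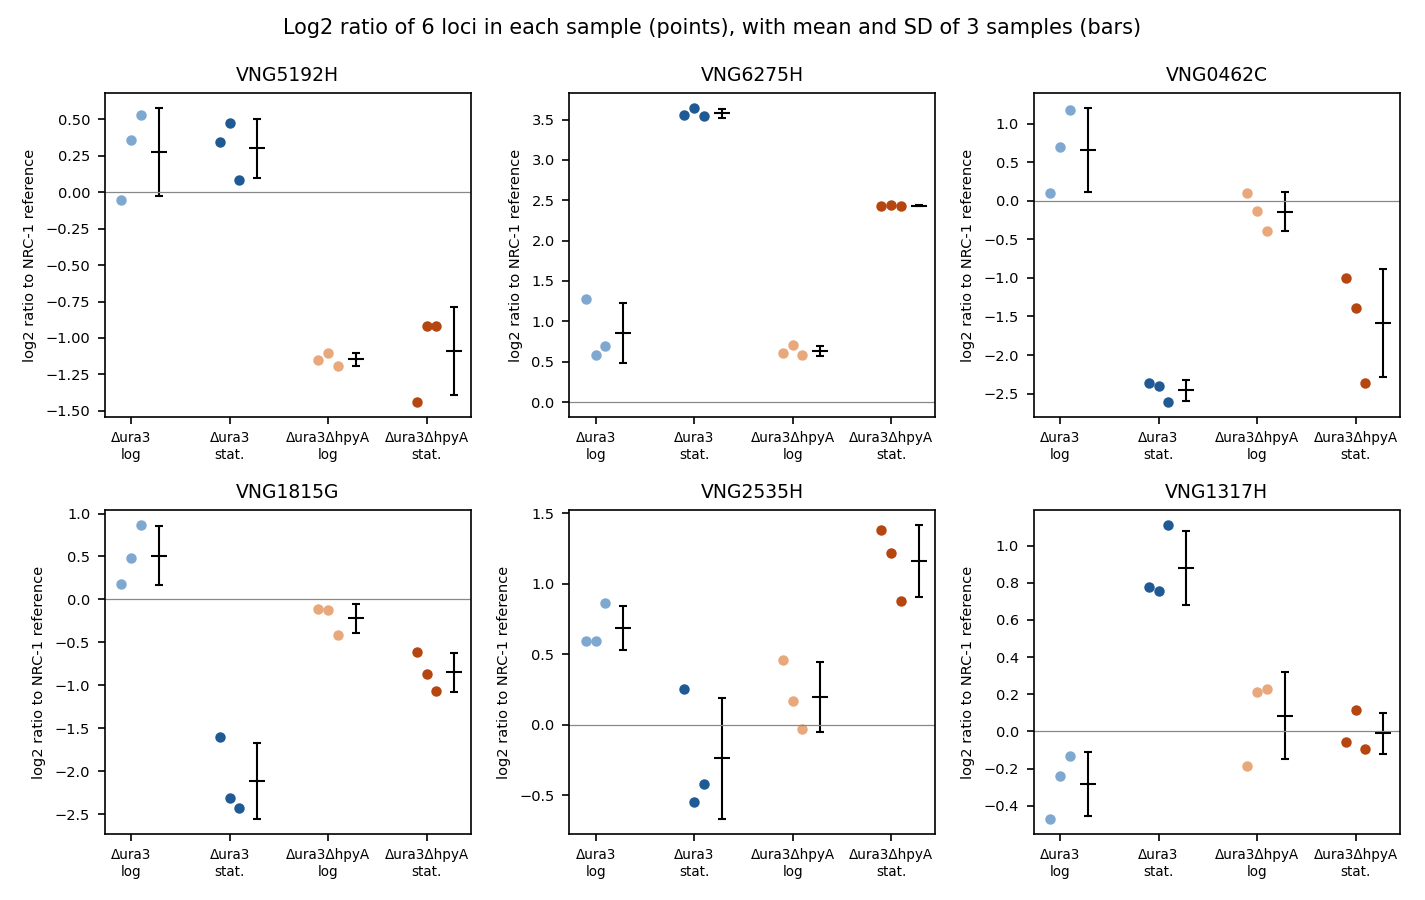
Log2 ratio to the NRC-1 reference of 6 loci in each of the 12 cultures, with 1 point per culture and bars for the mean and SD of 3 cultures, on a separate vertical axis for each locus. VNG5192H lies lower in the deletion strain in both phases, and the mean of VNG1815G goes from 0.51 to -2.11 in the parent and from -0.22 to -0.85 in the deletion strain. The stationary parent mean of VNG1815G lies near background, with 1 of 6 arrays well above it.

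In the parent strain 963 loci changed between log and stationary phase, 497 rising and 466 falling. VNG6275H rose from 0.86 ± 0.37 to 3.58 ± 0.05 (log2 ratio, SD, n = 3), a change of 2.72 (SE 0.14, adjusted p = 2.96e-06; 3.05, 2.84 and 2.27 by slide). VNG1920H rose from 0.34 ± 0.21 to 2.40 ± 0.23, by 2.06 (SE 0.13, adjusted p = 9.07e-06; 2.10, 2.33 and 1.74 by slide). The largest fitted falls were at loci with adjacent numbers, VNG0462C with -3.11 (SE 0.33, adjusted p = 0.000143; -3.09, -3.79 and -2.45 by slide) and VNG0463C with -2.88 (SE 0.31, adjusted p = 0.000143; -2.97, -3.53 and -2.13 by slide). Neither was well above background on any stationary parent array, and both were on all 6 log arrays, so the falls were at least 5.18-fold and at least 4.47-fold. Their rank among the falls therefore rests on the fitted values alone. The sizes depended on the processing, although each of these 4 loci was called in all of its 23 alternatives. The rise of VNG6275H was 1.59 with the authors' values and 1.46 with median centring, and that of VNG1920H was 1.14 with median centring. Without background correction the falls of VNG0462C and VNG0463C were -0.79 and -0.73, and with the scanner software's processed signals -4.63 and -4.28. Most changes were small: the median absolute change of the called loci was 0.39, and of the 157 loci with an absolute change of 1 or more, 19 rose and 138 fell.

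Of the 963 loci, 622 (64.6%) passed the filter on dim loci. Raw p was under 0.05 at 1271 loci, and the groups did not overlap at 48.9% of loci. Blocking on slide left 686 called loci, 275 rising and 411 falling. With the authors' values 743 rose and 431 fell, so the balance of directions depended on the fit and the processing. The count was 499 without parent stationary replicate 3, 513 without log replicate 3, 520 without log replicate 2, 579 without stationary replicate 1 and, as an alternative chosen after seeing the data, 162 without log replicates 2 and 3 together. VNG1673G, the deleted ura3 gene, was among the called loci as rising (adjusted p = 0.0488), although it was not well above background in the sample channel of any array, so no fold is given. It was called in 7 of 22 alternatives (adjusted p from 0.0109 to 0.353), not with slide as a block (0.0757), and not without parent log replicate 2 (0.0643) or 3 (0.166) or without stationary replicate 1 (0.0807), 2 (0.0886) or 3 (0.131).

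In the deletion strain 130 loci changed between the phases, 54 rising and 76 falling, with a median absolute change of 0.64. VNG1414G rose from 0.18 ± 0.18 to 2.55 ± 0.78 (SD, n = 3), by 2.38 (SE 0.34, adjusted p = 0.00290; 2.03, 1.76 and 3.34 by slide). It was not well above background on any log array of this strain and was so on 4 of 6 stationary arrays, so the rise was at least 2.23-fold. VNG6275H rose in this strain too, from 0.63 ± 0.07 to 2.43 ± 0.01, by 1.80 (SE 0.14, adjusted p = 0.000103; 1.82, 1.73 and 1.84 by slide). VNG5167H, a plasmid locus, fell from -0.42 ± 0.28 to -2.18 ± 0.67, a change of -1.76 (SE 0.28, adjusted p = 0.00535; -2.08, -1.30 and -1.90 by slide). VNG0462C fell from -0.14 ± 0.25 to -1.58 ± 0.70, a change of -1.44 (SE 0.33, adjusted p = 0.0318; -2.47, -1.25 and -0.61 by slide). Over the alternatives the changes went from 0.70 to 3.24 for VNG1414G, 1.27 to 1.90 for VNG6275H, -2.10 to -0.83 for VNG5167H and -1.86 to -0.44 for VNG0462C, the smallest for VNG1414G, VNG5167H and VNG0462C being without background correction. Without slide 1, VNG1414G (adjusted p = 0.0889, 5.2e-06 to 0.0889 over its 23 alternatives) and VNG5167H (0.0725, 3.87e-06 to 0.0725 over its 24 alternatives) were not called.

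Of the 130 loci, 108 (83.1%) passed the filter on dim loci, and 29 changed by 1 or more, 14 rising and 15 falling. Raw p was under 0.05 at 378 loci, and the groups did not overlap at 23.7% of loci. With slide as a block 82 loci were called, and VNG0462C was not (adjusted p = 0.0702, 0.00516 to 0.479 over its 24 alternatives). A block for replicate number, whose pairing in this strain rests on the data, ended that call too when fitted to all samples (adjusted p = 0.0615, 102 loci called). With the block applied to the deletion strain's samples alone, within the limma fit of all 12 samples, the call was kept (adjusted p = 0.0111, 171 loci called). This alternative was chosen after seeing that deviations in this strain correlated by number, so the kept call is no separate evidence. The count was 47 without log replicate 2, 71 without log replicate 1, 77 without log replicate 3 and 73 without stationary replicate 3. VNG0462C was not called without any one of these 4 samples (adjusted p from 0.0593 to 0.117).

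The phase changes of both strains were then set against each other, which share no sample. Of the loci called in each strain, 26 rose in both, where independent lists would share 11.1, and 73 fell in both, where they would share 14.7. A further 2 were called in opposite directions, 862 in the parent alone and 29 in the deletion strain alone. VNG6275H and VNG0462C were among the shared loci. Across all loci the changes correlated with r = 0.712 and rho = 0.541, with 0.873, 0.541 and 0.472 (r) and 0.741, 0.465 and 0.175 (rho) on slides 1, 2 and 3. Of the loci called in the parent, 85.2% had the same sign in the deletion strain. The changes were smaller in the deletion strain, with an SD across loci of 0.26 against 0.49 and a slope of 0.436, and with slopes of 0.696, 0.206 and 0.768 on slides 1, 2 and 3. Tested locus by locus, the difference between the phase changes is the third comparison above, with 5 called loci.

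**Figure D2:**
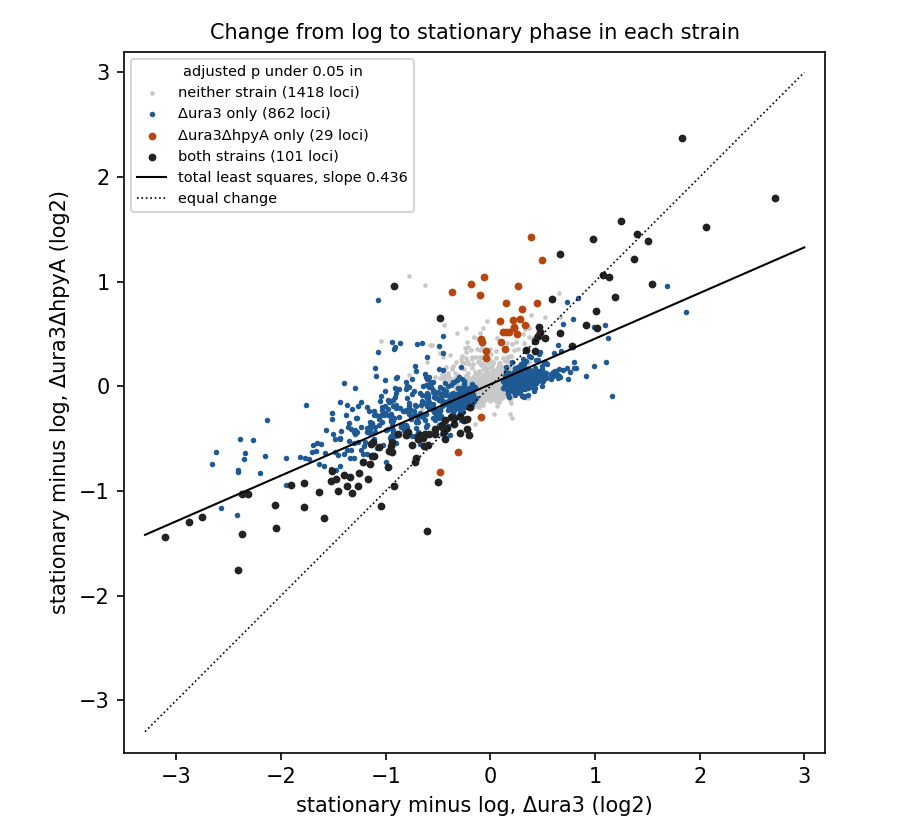
Change from log to stationary phase (log2) of 2410 loci in the Δura3 parent on the horizontal axis and in the deletion strain on the vertical axis, coloured by the strain in which the locus was called. The solid line is the total least squares slope of 0.436, and the dotted line marks equal change.

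The position of each culture on the axis from the log to the stationary mean described the same difference per culture. Log cultures lay at -0.291 ± 0.181 in the deletion strain and -0.658 ± 0.338 in the parent (SD, n = 3; two-sided exact permutation p = 0.2). Stationary cultures lay at 0.257 ± 0.272 and 0.7 ± 0.0926 (exact permutation p = 0.1, the smallest that 3 against 3 cultures allow). All 3 stationary parent cultures lay beyond all 3 stationary deletion cultures.

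**Figure D3:**
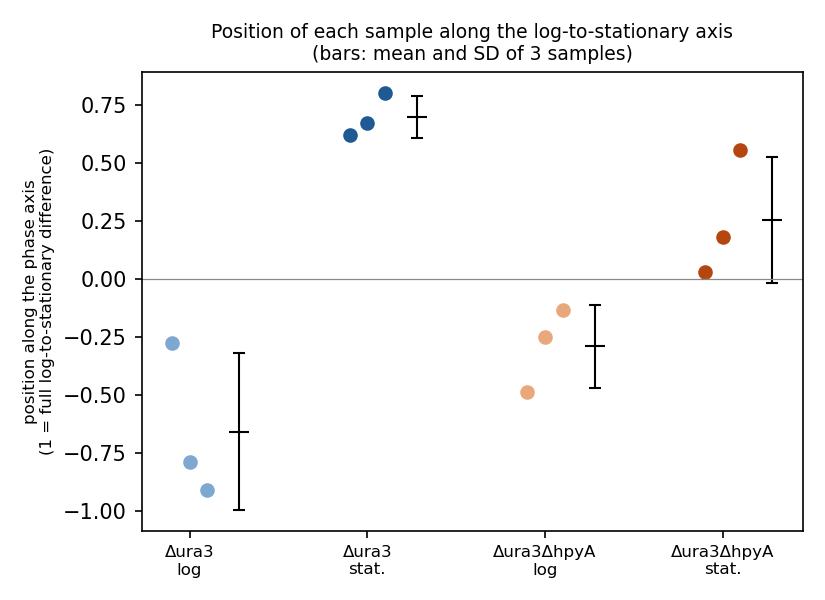
Position of each culture on the axis from log to stationary phase (points, 1 unit being the full difference between the phase means), with the mean and SD of 3 cultures per group as bars. The stationary deletion cultures lie nearer to 0 (mean 0.257) than the stationary parent cultures (mean 0.7).

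Across loci the strain difference in log phase and that in stationary phase correlated negatively, with r = -0.444 and rho = -0.529, and with r of -0.0744, -0.485 and -0.242 on slides 1, 2 and 3. VNG5192H was the locus called in both phases, lower in the deletion strain each time. The other 32 loci called in stationary phase were not called in log phase.

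The plasmid-borne loci, 355 of the 2410, were the gene list that could be tested. In the parent strain 162 of them changed with growth phase, 97 rising and 65 falling (172 adjusted over the list alone), which is 45.6% against 39% of the other 2055 loci (Fisher's exact p = 0.019, which takes loci as independent). The camera test, which allows for correlated loci, did not set the plasmid loci apart by a shift in 1 direction (camera p = 0.342, and 0.64 with the estimated correlation). It does not test the share that changed in either direction, so it does not bear on the Fisher comparison. VNG6275H was the largest rise among the plasmid loci. In the deletion strain 25 changed with phase, 10 rising and 15 falling (33 adjusted over the list alone), VNG5167H among them, or 7.04% against 5.11% (Fisher's exact p = 0.16). Between the strains, 1 plasmid locus was called in log phase (4 adjusted over the list alone), 6 in stationary phase, 3 higher and 3 lower (6 over the list alone), and 1 for the difference of differences (1 over the list alone).

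Tested as a set against the other loci with camera, the plasmid loci had p of 0.34 and 0.104 for the strain difference in log and stationary phase, 0.126 for the difference of these, and 0.342 and 0.545 for the phase change in the parent and the deletion strain. Blocking on slide gave p of 0.362, 0.114, 0.14, 0.35 and 0.574 in the same order, and with an estimated correlation p was 0.639, 0.43, 0.457, 0.64 and 0.765. Over loci that passed the filter on dim loci, p was 0.0342 in log phase (plasmid loci higher in the deletion strain), 0.0378 in stationary phase and 0.0126 for the difference (plasmid loci lower). With deletion stationary replicate 2 left out, the camera values of the latter pair were 0.0194 and 0.0433, and with parent log replicate 3 left out the direction in log phase turned (camera value 0.731). The mean shift of the plasmid loci against the others was -0.01, 0.10 and -0.01 on slides 1, 2 and 3 for the strain difference in log phase and -0.06, -0.01 and -0.05 in stationary phase. It was -0.05, -0.11 and -0.04 for the difference of these, 0.04, 0.10 and -0.03 for the phase change in the parent and -0.01, -0.01 and -0.07 for that in the deletion strain. Against no change, rather than against the other loci, a one-way fry test of the plasmid loci gave p of 0.313, 0.309, 0.173, 0.124 and 0.708, and its test of change in either direction gave 0.0703, 0.0627, 0.0349, 1.23e-05 and 0.00135. Median and mean of the plasmid loci had opposite signs in the stationary strain difference (-0.03 and 0.00214), the difference of differences (-0.05 and 0.00118), the parent's phase change (0.08 and -0.04) and that of the deletion strain (0.01 and -0.04), where camera pointed down, down, up and down.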

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

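The counts over other splits of the samples, the 4 tests on the log cultures and the 3 tests on the size of the phase change were chosen only after seeing the data. The bounds of the last 3 were written before the slopes they concern were computed, and the allowance of 1 SD afterwards. The limma test of whether the strain difference itself differed between the growth phases called 5 loci. Of these, 3 are printed, chosen by the size of the difference rather than by the smallest p. They were VNG1815G with 1.99, VNG2535H with 1.88 and VNG1317H with -1.26 (each adjusted p = 0.0379, with 3 cultures per group). VNG1815G fell less with phase in the deletion strain than in the parent. VNG2535H rose with phase in the deletion strain and fell in the parent, and VNG1317H rose in the parent and hardly moved in the deletion strain. Of these 3 loci, VNG1317H alone kept its call when slide was a block.

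Other splits of the same cultures were fitted in the same way. For the difference of differences, 100 of the 200 reassignments of the strain labels within phases were fitted, and 4 of these 100 gave 5 or more called loci, the real one included. That share lies under 0.05, but these reassignments took no account of the slides, so it cannot exclude chance. With slide as a block, 3 of the 32 ways to exchange the labels within slide and phase called 1 locus or more. The real assignment called 1 and the highest other also 1, so chance cannot be excluded there either. Among the 100 reassignments without slides, the highest other called 301 loci, many times the real 5, which points to a structure of the samples other than strain. For the remaining contrasts the 6 cultures make only 10 splits, too few for a share under 0.05. The real split gave 1 locus for the strain difference in log phase and the highest other gave 457, with 2 of 10 splits at 1 or more. In stationary phase the real split gave 33 and the highest other 2, for the phase change of the parent 963 and 1, and for that of the deletion strain 130 and 0, with 1 of 10 splits as high in each of these. In the deletion strain, 3 of the other splits part all 3 pairs of equal number, as the real one does, and called 0 loci, and the remaining 6 leave samples of a pair together.

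The split of the log cultures with 457 called loci put deletion replicate 1 with parent replicates 2 and 3, and the 8 other splits that mixed the strains called 0. Deviations from the group means correlated at -0.575 between the log cultures of slide 2, which argues against a slide effect there. On slides 1 and 3 they correlated at 0.337 and 0.684. Both log cultures of slide 1 lay on 1 side of the split and both of slide 3 on the other. An effect of these slides therefore cannot be told apart from other causes. A dye effect was argued against by the difference between both sets of cultures, which correlated at 0.731 between the dye orientations. This held although the dye-exchanged arrays of deletion replicates 2 and 3 and parent replicate 1 correlated at -0.253, -0.327 and -0.310. A different position between the phases cannot be told apart from other causes: the set with parent replicates 2 and 3 lay further from stationary phase on the phase axis (-0.489, -0.79 and -0.91 against -0.248, -0.135 and -0.275), an axis built in part from the other log cultures, while against the stationary ratios alone the differences between log replicates correlated at only -0.0311 in the deletion strain and -0.186 in the parent. Exchanged labels of deletion replicate 1 and parent replicate 1 cannot be told apart from the labels as given. Deletion replicate 1 correlated at 0.834 and 0.775 with parent replicates 2 and 3, and at 0.805 and 0.627 with deletion replicates 2 and 3. Parent replicate 1 correlated at 0.838 and 0.752 with deletion replicates 2 and 3, and at 0.632 and 0.487 with parent replicates 2 and 3. VNG5192H followed the labels (-1.15 against -0.06) but is a single dim locus. Of 24 loci called between the strains over the 10 other samples, 12 had the sign of their call between deletion replicate 1 and parent replicate 1. An exchange would alter every comparison that uses log cultures, and no biological explanation was tested.

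The change from log to stationary phase was smaller in the deletion strain, with a slope of 0.436 on the change in the parent (SD of 0.306 over 3 slides). Weaker signal on the arrays of the deletion strain was argued against by a slope of 0.546 over the 230 loci well above background in both channels on at least 20 arrays, and incomplete background removal by a slope of 0.371 with the scanner software's subtraction, both below the bound of 0.9 by more than that SD. Parent log cultures that lay unusually far from stationary phase cannot be told apart from an effect of the strain: the slope was 0.522 without parent log replicate 3 and 0.644 without replicates 2 and 3, and the latter was below 0.9 by less than the SD over slides, so that bound was not decisive. The loss of the histone gene, which the design names, therefore stays among the open explanations, and so does a difference in sampling point: the protocol names the same densities for both strains (OD600 of 0.5 in log and 1.5 in stationary phase), but no density or time of single cultures is recorded to test it.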

How the results depend on the processing

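The slope of the phase changes with all its alternatives, the restriction to bright loci, the replicate block in the deletion strain alone and the fit without parent log replicates 2 and 3 together were chosen after seeing the data. Counts are given in the order strain difference in log phase, in stationary phase, difference of these, phase change of the parent and of the deletion strain (1, 33, 5, 963 and 130 loci as reported), and where not stated the count was within 1.5 times the reported one. The folds printed for named loci kept their direction under every alternative run on them: 322 values kept their side of the threshold, 106 lost their call and 6 gained one. The mean ratio of VNG0134G, dim on every array, went from -0.02 to 0.02 with the scanner software's processed signals, and its folds were not recomputed. Of the counts of called loci, 79 moved by more than 1.5 times and 56 did not, and apart from the changes that follow from the number of samples, the threshold or the loci tested, the cause was not tested.

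The scanner software's processed signals gave 4 and 8 loci for the log strain difference and the difference of differences, moved the median of the latter to -0.126 and placed VNG1673G at -0.37 against -0.23. No background correction gave 3, 12 and 2 loci for the first 3 contrasts. Median centring gave 12 in stationary phase (10 higher, 2 lower) and 0 for the difference of differences. Scaling between arrays gave 65 (55 higher, 10 lower) and 11 for these. The authors' values gave 70 in stationary phase, 30 of them among the 33, and 743 rising and 431 falling loci in the parent. The filter on dim loci, with 984 loci tested, gave 2, 55 and 33. All 24 arrays with sample as a random block gave 13, 119, 157 and, in the deletion strain, 227. With only the contrast's groups in the fit, and so fewer samples behind the spread, there were 0 and 3 loci for the strain differences and 482 for the parent.

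A block for slide left 17 loci called in stationary phase (16 of the 33), 1 for the difference of differences and 82 in the deletion strain. Outside the phase change of the deletion strain the replicate numbers were taken to share only a number: deviations from the group means correlated between equal numbers at -0.813 to -0.109 for the log strain difference, 0.0255 to 0.383 in stationary phase and -0.594 to -0.18 for the parent's phase change. Over all 18 pairs they went from -0.813 to 0.74, and 3 of 12 samples correlated best with one of their own number. With replicate number as a block the counts were 22 in stationary phase, 3, 640 and 102 for the last 3 contrasts. The calls of VNG6224H (adjusted p = 0.0655) and VNG2451H (0.0764) in stationary phase, VNG1815G (0.0873) for the difference of differences and VNG1673G (0.069) in the parent ended under it. A replicate block in the deletion strain alone gave 28 loci for the difference of differences, with the 5 reported ones among them, and 171 in the deletion strain, with 127 of the 130.

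With each sample left out in turn the counts ranged from 0 to 247, 8 to 77, 0 to 441, 499 to 1339 and 47 to 142. Without slide 1 they were 0, 8, 0, 205 and 11, without slide 2 they were 0, 1, 0, 163 and 41, and without slide 3 they were 107, 19, 122 and, in the deletion strain, 205. Without parent log replicates 2 and 3 together, where the lone sample is assumed to vary like the other groups, they were 0 for the difference of differences and 162 for the parent. A minimum absolute log2 change of 1 gave 8 in stationary phase, 157 in the parent and 29 in the deletion strain. An adjusted p under 0.01 gave 0, 7, 0, 371 and 50. Beside these counts of 0 stand 269 loci (log phase) and 482 loci (difference of differences) with a raw p under 0.05 in the reported limma fit.

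The camera values of the plasmid list in the first 3 contrasts fell to 0.0342, 0.0378 and 0.0126 with the filter on dim loci, which tests fewer loci. With each sample left out in turn they ranged from 0.116 to 0.731, 0.0194 to 0.66 and 0.0433 to 0.481. Both lowest values of the last pair came without deletion stationary replicate 2, and without parent log replicate 3 (0.731) the direction in log phase turned. The phase changes of both strains correlated at 0.572 to 0.825 over the alternatives, the strain differences of both phases at -0.623 to -0.299, and the slope went from 0.335 to 0.644. The alternative that takes each probe of a gene by itself could not be applied, as each locus has 1 probe, and the median over probes became a median over spots. Low signal over background (a median of 34.8% of loci well above it in the sample channel) limits the folds of dim loci: a fitted fold against a group at background is no bound, and the lower bounds in the report were computed separately.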

Other observations

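The test of probe GC content on the strain difference in stationary phase was chosen only after that result had been seen; the other tests of this part were chosen before. Loci with adjacent numbers changed together more than shuffled loci did. Among the 963 loci called for the phase change of the parent, 51 runs of 3 or more adjacent loci changed in the same direction, with 168 loci in them, where 1000 shuffles gave a median of 98 and at most 150. Of these runs 29 rose (96 loci) and 22 fell (72 loci), and the longest held 6 loci. In the run from VNG2399H to VNG2404G, chosen after its values were seen, 5 loci fell in the parent by a mean log2 change of -0.85, while the mean in the deletion strain was 0.10 and the mean strain difference in stationary phase 0.61.

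The hypothesis that neighbouring loci share their change was tested as the correlation between 2388 adjacent pairs (numbers at most 3 apart) against 10000 shuffles. For the strain difference in stationary phase r was 0.17, above the highest shuffle of 0.0771 (permutation p = 1e-04, the smallest the shuffles can give), and 0.225 over the 454 pairs that passed the filter on dim loci. For the strain difference in log phase r was 0.0867, above the highest shuffle of 0.0725 (permutation p = 1e-04, the smallest they can give). For the phase change r was 0.0626 in the parent (permutation p = 0.001, highest shuffle 0.102) and 0.0401 in the deletion strain (permutation p = 0.03, highest shuffle 0.0799). The bound set beforehand for these, above all 10000 shuffles, was stricter than those p-values, so lying within the shuffles did not decide against a shared change.

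Regressing on GC content and length of the probes left r at 0.164 for the stationary strain difference and at 0.0626 for the parent's phase change, which argues against these probe properties as the cause. For the stationary strain difference the correlation was 0.175 between nearest loci on the list, 0.0237 at 2 places apart, and 0.033, 0.0472, 0.0543, 0.0501 and 0.0303 at 3, 5, 10, 20 and 50 places, and these weaker values were not tested. The 9 other splits of the stationary cultures gave 0.0372 and 0.0797 to 0.158, below the real 0.17. All but the lowest lay above the highest shuffle of 0.0771, so the shuffles alone do not tie the pattern to the strain. With 10 splits and this small margin, neighbouring loci that vary together between any cultures cannot be told apart from an effect of the strain. For the log strain difference no other splits were computed, so its shuffle result has the same limit. Genes transcribed together may account for the pattern, which the files give no operons to test, and a histone that acts on stretches of the chromosome stays open as well.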
